A study of Drosophila melanogaster with 8 samples.

How the data were processed

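Chromatin from adult Drosophila melanogaster testes was immunoprecipitated with an antibody to H3K27me3, the trimethylated lysine of histone H3 laid down by Polycomb repressive complexes, and sequenced beside input chromatin. The males were homozygous for a mutation in can or in comr and were 3 days old, with flies kept at 23 °C and 400 testes as the starting material, per the labels' protocols. The series holds 8 samples in 4 groups of 2 biological replicates: H3K27me3 in can, input in can, H3K27me3 in comr and input in comr. Libraries came from a small-input ChIP and amplification kit and were read on a MiSeq, a low-output instrument, per the labels' protocols.

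The authors deposited 1 profile per genotype, so the 2 replicates and their inputs stand behind a single value at each position. Per the file headers, each value is H3K27me3 divided by input in bins of 1000 bp, followed by a step abbreviated QN. The deposited score takes values on both sides of 0, from -5.58 to 4.27 with a median of 0, so it is on a log or centred scale. The base of that scale is not given in the sources used here, and differences of scores are therefore reported, never folds. The sorted values of the 2 profiles were identical, as quantile normalization of one profile to the other makes them. The profiles thus have the same distribution by construction, and a change in the total amount of H3K27me3 between genotypes cannot be read from them. The genome build was dm3, per the submitters' processing notes. The aligner, the read filters and the way replicates were combined are not given in the sources used here.

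Each profile had 1263776 rows at the same positions, 100 bp apart. Scores of rows 500 bp apart correlated at 0.60 in can and 0.63 in comr, and those 1000 bp apart at 0.21 and 0.28, so neighbouring rows share reads. Rows starting 500 bp into each kb were kept as non-overlapping 1 kb windows, 114670 of them on X, 2L, 2R, 3L, 3R and 4. Another 11708 windows lay on the 7 heterochromatic or unplaced sequences of dm3 (2LHet, 2RHet, 3LHet, 3RHet, XHet, YHet and U). Coordinates are those of dm3 as deposited, with each window taken as centred on its row. The read depth behind each score is unknown, so no counting interval could be given for a score.

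Enriched windows were the top 10% of windows on the 6 main sequences in each profile, at a score of at least 0.72 in can and 0.71 in comr. Enriched windows separated by gaps of at most 3 kb were joined, and stretches of at least 5 kb were called domains. A domain was shared when domains of the other genotype covered at least 50% of its length. The union of both sets gave the regions whose mean scores were compared. Errors beside a mean score are standard errors over the 1 kb windows of the region or SDs over 100 kb blocks with at least 20 windows. They describe scatter along the genome within 1 profile and not the spread between animals or libraries. With 1 profile per genotype there was no replicate check, no test across replicates and no p-value.

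For reference values, the comr profile was rotated along each chromosome 100 times, and the windows of each profile were shuffled within each chromosome 100 times. Window scatter was estimated from the SD of differences between adjacent windows divided by the square root of 2. In 20 simulated pairs, a common profile (the mean of both, smoothed over 11 windows) received independent normal scatter of that size. The domain caller was tested on simulated data with 100 domains raised by 0.9 in both profiles and 100 in either alone, over 114670 windows. It recovered 96 and 97 of the shared ones in can and comr, 97 of those planted in can and 95 of those planted in comr, and it called 0 and 1 of these in the wrong profile. The planted domains lay on the autosomal arms over a flat background, each longer than the median called domain of 7 kb. Real union domains averaged 0.48 to 0.54 in the profiles that called them. Calls outside planted domains were not counted, so recovery of shorter or weaker domains and false calls were not tested. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

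The thresholds, the rule for named regions and most alternatives were fixed before the data were examined. Without a gene annotation of the same build, that rule named the 10 longest domains of the union and the 5 with the largest difference in each direction. Counts of domains of at least 20 kb, 1 Mb regions, the alternatives that left out X or set thresholds within each sequence, and those that used other rows were added afterwards. Gene-level comparisons had also been planned, for 12 lists that covered Hox genes, other Polycomb targets, spermatid genes, regulators of the testis programme and markers of other cell types. The gene table at hand follows the Release 6 assembly, so none of these lists was analysed here, and no region was given a gene name.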

Results

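H3K27me3 was profiled in testes of can and comr mutant males, which lack regulators of the transcription programme of primary spermatocytes. can (cannonball) encodes a testis-specific homologue of a TBP-associated factor (a tTAF), and comr (cookie monster) encodes a subunit of the testis-specific meiotic arrest complex (tMAC). Germ cells of both mutants arrest as spermatocytes and do not form spermatids. The design sets the histone mark in one mutant beside that in the other, each with 2 H3K27me3 libraries and 2 inputs that had been combined into 1 normalized profile. No wild-type profile was analysed here. Scores are H3K27me3 over input, and the read depth behind them is unknown.

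In both mutants the score was highest on X, near 0 on the large autosomal arms and lowest on chromosome 4 and in heterochromatin. X had a mean score of 0.13 in can and 0.07 in comr, against 0.01 in both over the 4 arms 2L, 2R, 3L and 3R. Chromosome 4, the small dot chromosome with heterochromatin-like packaging, had a mean of -0.35 in can and -0.53 in comr. The heterochromatic sequences 2LHet, 2RHet, 3LHet and 3RHet, which hold mapped parts of the pericentric regions, averaged -0.28 in can and -0.19 in comr. The unplaced sequence U stood at -0.26 in can and -0.12 in comr. The SD over 100 kb blocks was 0.18 in can and 0.21 in comr on X (n = 223 blocks), and 0.16 in both on chromosome 4 (n = 13 blocks). The X excess over the autosomal arms was 0.12 ± 0.01 in can and 0.07 ± 0.02 in comr, and the deficit of chromosome 4 was -0.35 ± 0.04 and -0.54 ± 0.05 (standard errors over blocks, which treat neighbouring blocks as independent). Outside called domains, the X excess was 0.02 in can and -0.01 in comr. Domains were picked by high score and covered more of X than of the arms, so part of this fall follows from the selection.

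**Figure D1:**
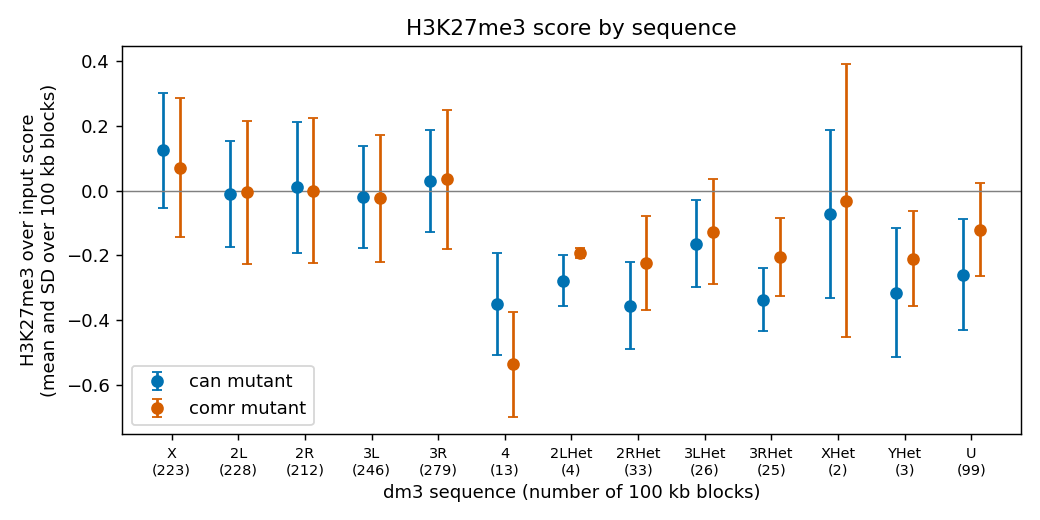
Mean H3K27me3 over input score (vertical axis, log or centred scale of unstated base) of each dm3 sequence in can (blue) and comr (orange), with points for means and bars for SDs over 100 kb blocks, whose number stands under each name. Chromosome 4 lies at -0.35 in can, beside 2RHet at -0.35, and lowest of the sequences in comr at -0.54, and the means of the 7 heterochromatic or unplaced sequences lie below 0.

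The 2 mutants differed in opposite directions on these low-scoring sequences. On chromosome 4 all 13 blocks were lower in comr, with a mean difference of -0.19 ± 0.06 (SD, n = 13 blocks). On 2LHet, 2RHet, 3LHet and 3RHet together, 75 of 88 blocks were higher in comr, by 0.10 ± 0.10 on average (SD, n = 88 blocks). All 25 blocks of 3RHet and 30 of 33 blocks of 2RHet were higher in comr, by 0.13 ± 0.08 and 0.13 ± 0.10 (SD). On 3LHet the shift was smaller and less uniform, with 17 of 26 blocks higher in comr, by 0.04 ± 0.10 (SD). On U, 82 of 99 blocks were higher in comr, by 0.14 ± 0.14 (SD). On X, 147 of 223 blocks were lower in comr, with a mean difference of -0.05 ± 0.14 (SD, n = 223 blocks). The 4 autosomal arms divided almost evenly, with 466 blocks lower and 499 higher in comr. Blocks of 1 profile are not replicates, so these counts describe how uniform a difference was along a sequence and not whether it would recur in other animals. The normalization also gave both profiles the same mean over all rows, so lower scores in comr on some sequences must be offset by higher ones elsewhere. The opposite directions are therefore not independent results.

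Along the chromosomes the mutants shared the broad distribution of H3K27me3. Over 120 regions of 1 Mb the mean scores of can and comr correlated at r = 0.92 across regions (Spearman's rho = 0.93), which are not independent replicates. The regions named here were chosen after their values were seen. By the mean of both profiles, the 1 to 2 Mb region of X stood highest, with 0.42 in can and 0.35 in comr. The 20 to 21 Mb region of 2R followed, with 0.39 in can and 0.30 in comr, and the 18 to 19 Mb region of X with 0.29 and 0.26. Apart from chromosome 4, the lowest were the first 2 Mb of 2R, next to the centromere, with -0.32 and -0.30 in the first Mb and -0.26 in both mutants in the next. The 1 Mb regions with the largest deficits in comr, chromosome 4 aside, were 19 to 20 Mb of X, with 0.25 in can and 0.05 in comr, and 27 to 28 Mb of 3R, with 0.30 and 0.10. Their differences were -0.20 ± 0.03 and -0.19 ± 0.02 (standard error over 926 and 864 windows). The largest excess in comr was 0.09 ± 0.02 (standard error over 976 windows), at 11 to 12 Mb of 2L, where the scores were 0.07 in can and 0.15 in comr.

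At finer scale the agreement fell. The correlation across bins was 0.85 in bins of 100 kb, 0.66 in bins of 10 kb and 0.31 in windows of 1 kb. Rotating the comr profile along the chromosomes gave a mean r of 0.01 at 1 kb, with -0.01 to 0.02 over 100 rotations. X was less correlated than the autosomal arms at each bin size, with 0.22 against 0.34 at 1 kb and 0.76 against 0.87 at 100 kb. Window scatter was also wider on X, with an SD of 0.65 in can and 0.64 in comr, than on the autosomal arms, with 0.46 and 0.45.

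**Figure D2:**
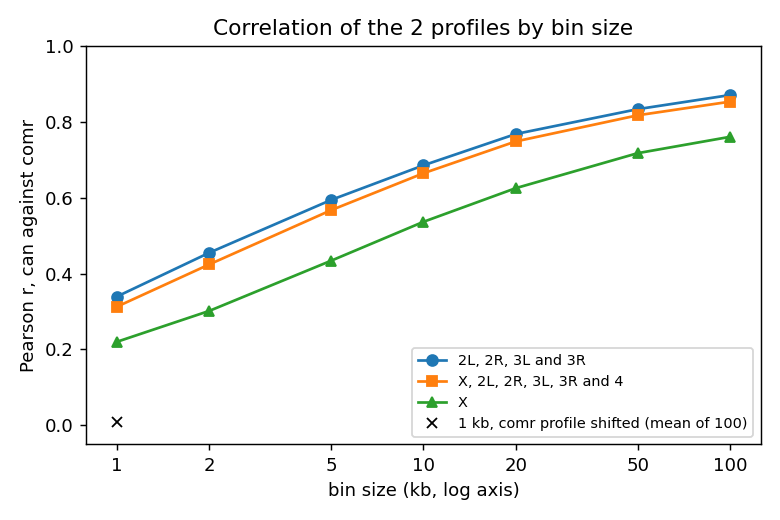
Pearson correlation of the can and comr scores (vertical axis) against bin size in kb (horizontal log axis), for the autosomal arms, the 6 main sequences and X, with the mean of 100 rotated comr profiles as a cross. Over the 6 main sequences r rises from 0.31 at 1 kb to 0.85 at 100 kb, and X lies below the arms throughout.

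Long H3K27me3 domains were present in both mutants, with a higher count in comr at the main threshold. Domains of at least 20 kb numbered 37 in can and 86 in comr, against 5 to 23 and 2 to 14 when windows were shuffled within chromosomes. The gap between the mutants depended on the threshold, with 10 against 13 at the top 5% of windows and 268 against 333 at the top 20%. X carried 24 of the 37 in can and 33 of the 86 in comr. Domains of comr covered 24 of the 37 long can domains over at least 50% of their length, and domains of can covered 37 of the 86 long comr domains. With all lengths from 5 kb included, 1234 domains spanned 10.3 Mb in can and 1248 spanned 11.8 Mb in comr. Shuffled windows gave 1088 to 1216 domains for can and 1121 to 1247 for comr, with means of 1149 and 1167, so the numbers observed lay just above the shuffled ranges. The excess lay on the autosomal arms, with 726 domains in can against 553 to 692 shuffled and 836 in comr against 675 to 770. On X, 501 domains in can lay below the shuffled 505 to 582, and 410 in comr lay within 399 to 477.

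Sharing of domains and enriched windows exceeded that of rotated profiles but was incomplete. Of the 1234 can domains, 390 (31.6%, 95% Wilson interval 29.1 to 34.3) were covered by comr domains, against 10.5 to 14.7% in 100 rotations. Of the 1248 comr domains, 328 (26.3%, 95% Wilson interval 23.9 to 28.8) were covered by can domains, against 8.4 to 13.0%. Of the 20481 windows enriched in either profile, 2876 (14.0%, 95% Wilson interval 13.6 to 14.5) were enriched in both, against 5.5 to 6.5%. The intervals treat domains and windows as independent and cover counting error only. In pairs simulated from 1 common profile with independent scatter, 28.1 to 33.0% of can domains and 28.6 to 31.5% of comr domains were covered. Unshared calls are therefore not by themselves domains particular to 1 mutant. X contributed 41% of the can domains and 33% of the comr domains, and 18.7% of its windows were enriched in can and 16.5% in comr, against 8.2% and 9.0% on the autosomal arms. On X 38.3% of comr domains were covered by can domains, against 20.3% on the arms. For can domains the shares were 33.7% and 30.3%. With more of X enriched, more overlap arises there without agreement, and rotations were not split by chromosome.

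The union joined overlapping calls of the 2 profiles, so its domains could be longer than any single call, whose longest was 55 kb in can and 77 kb in comr. The 10 longest domains of the union spanned 61 to 105 kb and each held calls of both mutants, which joining of overlapping calls favours in the longest. They had mean scores of 0.42 to 0.75 in can and 0.55 to 0.81 in comr. High scores in them follow in part from the choice by enriched windows. The longest, on X from 4267050 to 4372049 (105 kb), scored 0.64 ± 0.06 in can and 0.63 ± 0.06 in comr (standard error over 105 windows). The domain on X from 18099050 to 18187049 (88 kb) scored 0.62 ± 0.06 in can and 0.74 ± 0.07 in comr. The domain on X from 1294050 to 1375049 (81 kb) scored 0.75 ± 0.06 in can and 0.61 ± 0.06 in comr. On 2R, the domain from 20680050 to 20757049 (77 kb) scored 0.70 ± 0.05 in can and 0.81 ± 0.05 in comr. The second long 2R domain, from 18101050 to 18173049 (72 kb), scored 0.67 ± 0.06 in can and 0.76 ± 0.05 in comr. In each of these 5 domains the difference between mutants was less than 2 of its standard errors.

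**Figure D3:**
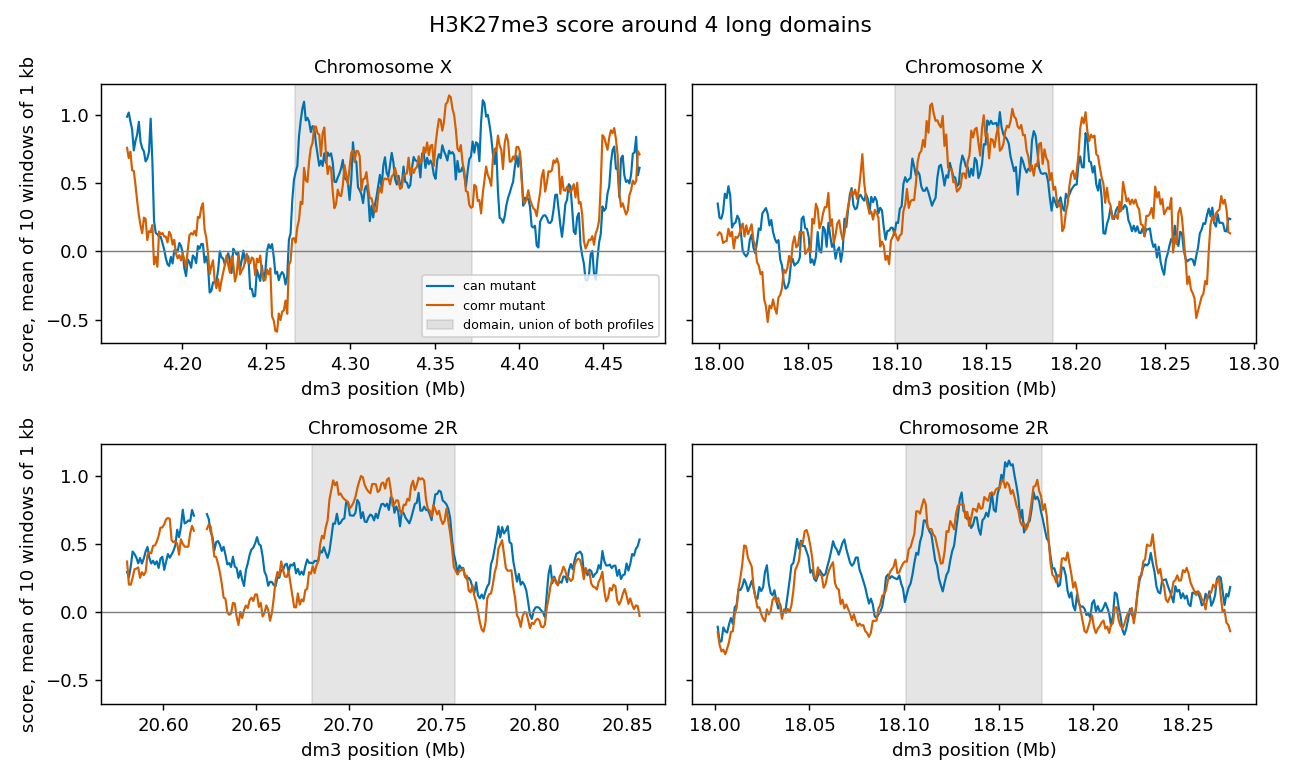
Running mean of 10 windows of 1 kb of the H3K27me3 over input score (vertical axis) against dm3 position in Mb in can (blue) and comr (orange), for the 2 longest domains of the union on X and the 2 longest on 2R, with 100 kb on either side; grey marks the domain. The 2 profiles rise at the same places, to domain means of 0.62 to 0.70 in can and 0.63 to 0.81 in comr, in regions chosen for enriched windows.

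Among the other 5 of the 10 longest, 4 were higher in comr by more than 2 standard errors over windows. On 3R, the domain from 17240050 to 17307049 (67 kb) scored 0.55 in can and 0.79 in comr, a difference of 0.24 ± 0.06. On X, the domain from 9598050 to 9675049 (77 kb) scored 0.42 and 0.70, a difference of 0.29 ± 0.09. The X domain from 5423050 to 5491049 (68 kb) scored 0.48 and 0.78, a difference of 0.30 ± 0.12. On 3L, the domain from 22439050 to 22500049 (61 kb) scored 0.43 and 0.55, a difference of 0.12 ± 0.05. The remaining one, on X from 18469050 to 18536049 (67 kb), scored 0.53 in can and 0.66 in comr, a difference of 0.13 ± 0.10. How far such differences exceed the spread between replicate libraries could not be examined. More of the long calls behind the union came from comr, so the choice by length favoured domains with high comr scores. The excesses in comr are in part a result of that choice.

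The union held 139 domains of at least 20 kb, many of them long through this joining, and 128 held some call of each mutant. A call of at least 20 kb lay in 33 of them in can, in 83 in comr, in 14 in both and in 37 in neither. All 139 had a mean above 0 in both profiles, which the choice by enriched windows largely fixed where both mutants had calls. On the autosomal arms 67 of 78 scored higher in comr, and on X 39 of 61 did. Since comr had more long domains, it weighed more in choosing this set. The largest differences among these 139 domains, picked after their values were seen, lay on X for losses in comr and on the autosomal arms for gains. The X domain from 20253050 to 20277049 (24 kb) scored 0.73 ± 0.12 in can and 0.21 ± 0.11 in comr. The X domain from 19354050 to 19392049 (38 kb) scored 0.48 ± 0.11 in can and 0.01 ± 0.09 in comr. In the other direction, the 3R domain from 25509050 to 25541049 (32 kb) scored 0.35 ± 0.08 in can and 0.82 ± 0.08 in comr. The 3R domain from 6480050 to 6500049 (20 kb) scored 0.36 ± 0.09 in can and 0.83 ± 0.11 in comr.

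The largest differences over all 1898 union domains fell in short ones, of 5 to 7 kb and 2 to 7 windows, each called in 1 mutant. The 2R domain from 12349050 to 12354049 scored -0.65 ± 0.35 in can and 0.66 ± 0.29 in comr, an excess of 1.31 ± 0.18. The X domain from 12337050 to 12344049 scored 1.19 ± 0.29 in can and -0.53 ± 0.48 in comr, a difference of -1.72 ± 0.58. The other 4 excesses were 1.17 to 1.28 and lay on 2R (from 10775050 to 10781049) and on X (from 7364050, 3537050 and 6817050). The one from 3537050, at 1.21 ± 0.72, was less than 2 standard errors from 0. The other 4 deficits were -1.42 to -1.70 and lay on 3L (from 24362050), 3R (from 26903050) and X (from 159050 and 8900050). Only the one from 8900050, at -1.42 ± 0.39, was more than 2 standard errors from 0. The others were -1.70 ± 1.28 on 3L (3 windows), -1.42 ± 1.51 on 3R (2 windows) and -1.44 ± 0.87 on X. Size and rank depended on the rows used: with rows starting at each kb, the 2R domain from 10775050 moved from 1.28 to 2.60 and passed the one from 12349050, at 1.40. The X domain from 3537050 moved from 1.21 to 0.43, the 3L domain from -1.70 to -0.40, and the X domains from 159050 and 8900050 from -1.44 to -0.55 and from -1.42 to -0.94. The 3R domain had no value with those rows. Pairs simulated from 1 common profile with independent window scatter reached 1.15 to 2.07 at the upper end and -1.15 to -1.73 at the lower end in 20 draws. These pairs agreed less than the observed profiles in 1 kb windows, with r of 0.21 to 0.22 against 0.31. The 691 domains called in can alone averaged 0.51 in can and 0.13 in comr, with 475 above 0 in comr. The 731 domains called in comr alone averaged 0.54 in comr and 0.19 in can, with 564 above 0 in can. For reference, the median over all rows was 0 in both profiles. A domain called in 1 mutant alone could still hold enriched windows of the other, in stretches shorter than 5 kb.

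**Figure D4:**
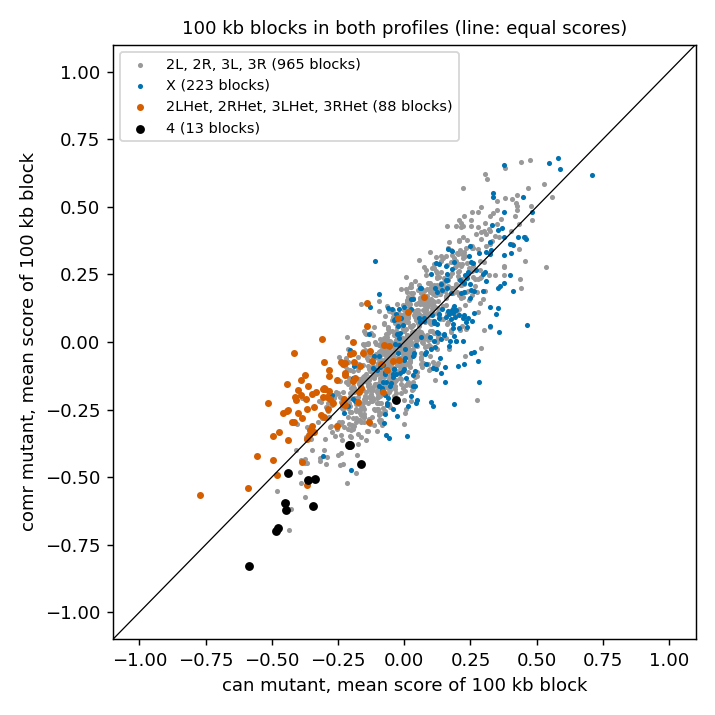
Mean H3K27me3 over input score of 100 kb blocks in can (horizontal axis) and comr (vertical axis), coloured by sequence, with the line of equal scores. All 13 blocks of chromosome 4 lie below the line and 75 of the 88 heterochromatic blocks lie above it.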

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

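Alternatives that left out X, used other rows or set thresholds within each sequence, and all those for domains of at least 20 kb, were added after the data were seen. No paired analysis was possible because the 2 replicates of each genotype were deposited as 1 combined profile, and replicates could not be left out. The planned gene-level and gene-list alternatives, with their windows, thresholds and pseudocounts, were not run for want of an annotation of the build. The correlation of 0.31 was 0.57 in 5 kb bins, 0.32 with all sequences and 0.34 without X. Shared enriched windows (14.0%) came to 9.1% at the top 5%, 22.0% at the top 20%, 13.6% with rows starting at each kb and 14.6% without X. Domains in can and comr (1234 and 1248) numbered 447 and 488 at the top 5%, 2660 and 2441 at the top 20%, 318 and 370 with a minimum of 10 kb, and 30 and 73 with no gaps joined. Domains of at least 20 kb (37 and 86) numbered 10 and 13 at the top 5%, 268 and 333 at the top 20%, and 0 in both with no gaps joined. They numbered 29 and 64 without X and 32 and 75 with thresholds within each sequence, and comr had more under every setting that gave any, by a smaller ratio at the top 5% and 20%. Coverage of can domains by comr (31.6%) was 42.8% for any overlap, 19.7% for at least 80%, 19.2% at the top 5% and 45.1% at the top 20%. Coverage of comr domains by can (26.3%) was 40.1%, 13.7%, 16.0% and 44.2% under the same settings, and 23.4% with thresholds within each sequence. Outside enriched domains the X excess fell from 0.122 to 0.0227 in can and from 0.0683 to -0.0119 in comr, where it reversed. Domains were picked by high score and covered more of X than of the arms, so some fall was built in. Any further cause was not tested. The difference on chromosome 4 was -0.15 as a median. Of 39 recomputed differences of named domains, 6 moved by more than their standard error, and 1 changed sign near 0: the longest domain, from -0.0032 to 0.0069 with all overlapping rows. Unknown depth and the lack of separate replicates limit each of these values.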

Other observations

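The tests of window variance on X and those on chromosome 4 and the heterochromatic sequences were chosen after the results were seen, and the others were set beforehand, although the test of X blocks was divided by profile after its result was seen. On 2L, 2R, 3L and 3R the Mb of mapped sequence next to the centromere averaged below the rest of the arm in can and comr alike, by an amount that differed between arms. On 2R it averaged -0.32 in can and -0.31 in comr, against 0.03 and 0.02 over the rest of the arm, and none of the other 20 Mb regions was lower. On 2L it averaged -0.14 in can and -0.13 in comr, against 0.00 in both, and 3 of the other 22 Mb regions were lower in each profile. On 3L it averaged -0.11 in both against -0.01 in can and -0.02 in comr, and 4 of 24 regions in can and 7 in comr were lower. On 3R it averaged -0.06 in can and -0.13 in comr, against 0.03 and 0.04, and 3 of 27 regions in can and 1 in comr were lower. X differed least, with 0.07 in can and 0.06 in comr near the centromere against 0.13 and 0.07 elsewhere, and 7 of its other 21 Mb regions in can and 11 in comr were lower still.

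Extreme scores were almost never shared between profiles. Each profile held 426 rows at or below -3, of which 1 was shared, and 171 rows at or above 3, of which 0 were shared. The equal counts follow from the normalization. So few of 1263776 rows would hardly overlap at random either, so these counts do not show that sharing was less than random. U held 258 of the 426 lowest rows in can and 116 in comr, and X held 112 of the 171 highest rows in can and 96 in comr. In the 20 pairs simulated from 1 common profile, 28.1 to 33.0% of can domains were covered in comr, against 31.6% observed. For comr domains the simulated share was 28.6 to 31.5%, against 26.3% observed, and the simulated r over 100 kb bins was 0.93 to 0.94, against 0.85 observed. At fine scale the observed profiles agreed better than the simulated ones, with r of 0.31 against 0.21 to 0.22 at 1 kb and 14.0% against 10.6 to 11.4% of enriched windows shared. That was largely built in: smoothing over 11 windows removed shared fine structure from the common profile, and differences of adjacent windows counted it as scatter. At broad scale the profiles differed by more than window scatter: the variance of the difference between mutants was 2.26 times that given by the scatter of windows within bins at 50 kb and 2.97 times at 100 kb. Whether replicate libraries of 1 genotype would differ as much could not be examined.

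X was over-represented among enriched windows, and the variance of its window scatter was 1.964 times that of the autosomal arms in can and 2.02 times in comr, close to the ratio of 2 that 1 copy of X in males, with fewer reads per window, may give. Chromosome 4, an autosome, also had a wider scatter, with 1.41 times the variance of the arms in can and 1.31 times in comr. Wider scatter is thus not particular to X, and the match does not settle its cause. With the X mean set to that of the arms and its scatter kept, 14.2% of X windows in can and 13.8% in comr would be enriched, against 8.2% and 9.0% on the arms, so most of the excess came with the wider spread of X windows, in which scatter and real domains were not separated. Scatter was not the whole cause in can: in means over 100 kb, where scatter is small, X still held 47 of the top 121 blocks. That was 2.09 times its share of blocks (95% Wilson interval 1.65 to 2.57). In comr X held 32 of 121, a ratio of 1.42 (interval 1.04 to 1.88). That is more than its share, which scatter alone would not give, but below the level set beforehand for a clear answer. Both intervals treat neighbouring blocks as independent. The comr value thus argues against scatter as the whole cause, but more weakly than the can value. Each X window was also shrunk toward the X mean by the ratio of scatter on the arms to that on X. That left 10.97% of X windows enriched in can and 8.7% in comr. The step shrinks real domains as well as scatter, so the share falls whatever the cause. The comr value therefore does not show that an excess is absent. A higher level of H3K27me3 on X, in can and less clearly in comr, stays open as an untested biological explanation.

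The larger number of long domains in comr went with a wider spread of its 100 kb block means. Their SD over the autosomal arms was 0.17 in can and 0.21 in comr. The SD over all rows was the same in both profiles, 0.59, as the normalization makes it. A candidate explanation is a stronger contrast between blocks in comr, as a less noisy or better enriched library would have. The SD over autosomal blocks was 1.26 times that in can. After the normalization, such a contrast could show only in how scores are arranged along the chromosomes and not in their total spread. In the bottom 10% of autosomal blocks the mean difference was -0.071 (72 of 97 lower in comr), and in the top 10% it was 0.084 (78 of 97 higher). This does not decide: with equal autosomal means and the wider spread of block means already known, the outcome was largely fixed. Contrast of the libraries and an effect of genotype cannot be told apart with 1 profile each.

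Chromosome 4 and heterochromatin moved in opposite directions between the mutants. The normalization gave both profiles the same mean over all rows, so gains and losses must balance. A shift on a given sequence may thus in part offset shifts elsewhere. Scatter of windows does not give 13 of 13 blocks of chromosome 4 lower in comr. The stronger contrast between blocks in comr, if it scaled all scores alike, would bring chromosome 4 to -0.43, whereas it scored -0.53. The remainder was -0.097, with a standard error of 0.017 over block differences on chromosome 4. That error leaves out the uncertainty of the contrast itself and of applying it from the autosomal arms to chromosome 4. The size of the remainder in such errors therefore does not measure how firmly contrast is excluded. The same contrast would take the heterochromatic sequences from -0.28 to -0.35, whereas 75 of 88 blocks were higher in comr and the mean was -0.19. Differences in GC content, repeats or mapping between libraries were not tested, since no genome sequence was used here, and they could produce such shifts as well as a difference between the genotypes. Which of these holds stays open.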
